A study of Homo sapiens with 4 samples.

How the data were processed

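RNA was measured in 4 libraries of LNCaP, a human prostate cancer cell line: 2 of control cells and 2 of cells overexpressing the ETS-family transcription factor ETV5 (ETV5_OE). Per the labels' protocols, total RNA was extracted with TRIzol, libraries were made with a TruSeq RNA kit and sequenced as paired ends on a NovaSeq instrument. The labels do not say what separates the replicates of a group, and the library names of the ETV5_OE pair share a stem. The p-values therefore measure only the spread between these libraries, which may be technical.

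The deposited table lists 17902 genes, of which 13018 are annotated as protein coding, by symbol, gene ID and RefSeq transcript. Per the submitters' processing notes, Trimmomatic, HISAT2, StringTie and the hg38 build were used; the notes as used here give no versions, no roles and no strand setting. Per the file headers, the table holds raw read counts per gene, which were whole numbers with different totals in each library, and no library was pooled. Every listed gene has at least 1 read in all 4 libraries, so genes without a read in any one of them are not analysed here. This removes genes switched fully on or off by ETV5 from every result. Per the file headers, the authors also deposited FPKM values, which divide the counts by transcript length and library size. The deposited group means are on a log2 scale: they equalled the mean of quantile-normalized log2(FPKM + 1) to within 0.000508. The deposited fold is the signed linear fold of those means, with control over ETV5_OE written as a negative number. The deposited p-values are unadjusted per the file headers, and the authors' test is not given in the sources used here.

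Total counts were 30227070 and 20639543 in Control replicates 1 and 2, and 22369062 and 24642392 in ETV5_OE replicates 1 and 2. The structural RNAs RN7SL1, RN7SL2, RN7SK, RPPH1 and RMRP together took 14.6% and 15.7% of the counts in the control libraries and 15.0% and 16.8% in the ETV5_OE libraries. Gene coordinates came from the RefSeq annotation of GRCh38.p14, the same build as hg38, matched by gene ID for 17561 genes (98.1%). Counts of near-identical paralogs, such as the UGT2B genes, depend on how shared reads were assigned, and are uncertain.

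The following choices were made before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3: genes passed the default expression filter (minimum count 10), libraries were scaled by TMM, and a robust quasi-likelihood F test compared ETV5_OE with Control. Benjamini-Hochberg adjusted p-values under 0.05 were called. The filter kept 16194 genes and left 1708 untested. Standard errors of log2 fold changes were taken from the fold change and the F statistic. Means and SDs are of CPM, the count per gene normalised to library size, over n = 2 libraries per group. The text names ETV5, PBX3 and TLL1, and the 8 largest rises and 8 largest falls among called genes. The latter needed a mean CPM of at least 1, groups that do not overlap, and a symbol that is not a LOC, pseudogene, antisense or clone name. It also names up to 3 members with the smallest adjusted p in each list below, and may leave out those that did not pass. Other genes named below were chosen after their values were seen.

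Gene lists were fixed for luminal prostate epithelium, basal epithelium, neuroendocrine markers, neuroendocrine prostate cancer (NEPC) score genes, neural stem and progenitor genes, neuronal cytoskeleton and synapse genes, axon guidance, MAPK output and feedback, PEA3 and ETS invasion targets, mesenchymal genes, the Notch pathway, Wnt target genes, pluripotency and stemness, S phase genes, G2 and M phase genes, the type I interferon response, sterol synthesis, the amino acid stress response, the ER unfolded protein response, hypoxia and glycolysis, and p53 targets. The others were stromal, endothelial and immune markers, immediate early genes, mitochondrially encoded genes, cytosolic ribosomal proteins and replication dependent histones. Results for a further 3 lists, and for some single genes, are not reported here. Each of the 29 lists was tested with camera in limma 3.58.1, two-sided, on log2 CPM with a prior count of 2. Camera compares a list with the other genes, here with a preset correlation of 0.01 between genes, and p-values were adjusted over all 29 lists. Camera with an estimated correlation, and fry, which asks whether a list moves one way without comparing it with other genes, were alternatives. The members called were also counted after adjustment over the list alone.

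Further alternatives were DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with genes at FPKM 1 or more in 2 libraries, RLE, upper-quartile and total-count scaling, no filter and a CPM filter of 1 in 2 libraries, the fit without robust estimation, a test against a 1.5-fold change (glmTreat), the replicate number as a block, and leaving out each library in turn. When a library is left out, the lone sample of its group is assumed to vary like the other group. Offsets for GC content and transcript length, leaving out small structural RNAs, and upper-quartile scaling for the list tests were added after the data were seen.

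The pair of control libraries differed by 12.0 times the counting noise (median chi-square over its expected value) and the ETV5_OE pair by 9.30 times. Pairs across the groups differed by 10.9 to 13.1 times, so no library was counted as a duplicate. The test was tried on simulated counts for 16194 genes with the means and sizes of these libraries, with 200 genes changed, 50 per fold size. It recovered 0% of genes changed 1.5-fold, 32% at 2-fold, 90% at 4-fold and 100% at 8-fold, and 11.2% of its calls fell on unchanged genes. With nothing changed it made 7 calls. A planted list of 30 genes lowered 1.5-fold had an adjusted camera p of 2.86e-26, against 0.992 with an estimated correlation and 0.539 with fry, and 0 of 100 random lists passed with camera. Genes were drawn independently of each other, so camera was not tried on lists whose members vary together.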

Results

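Gene expression was measured by RNA sequencing in LNCaP cells, a line from a prostate cancer metastasis, with 2 control libraries and 2 libraries of cells overexpressing ETV5 (ETV5_OE). The labels give 1 comparison, ETV5_OE against Control. It asks which genes change when this ETS factor is raised in these cells, in a study concerned with neuroendocrine prostate cancer and neural stem-like differentiation. Depth ranged from 20639543 to 30227070 counts per library. Of 16194 genes tested, 65 passed the threshold with edgeR, 41 higher and 24 lower in ETV5_OE, and 64 of them were protein coding. At an unadjusted p under 0.05, 588 genes were higher and 568 lower. On simulated counts, 11.2% of the calls at the adjusted threshold fell on unchanged genes, so calls near 0.05 are less certain than the threshold states.

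ETV5 itself was higher in both ETV5_OE libraries than in either control. It had 22 and 27 counts in the control libraries and 534 and 522 in the ETV5_OE libraries. Its level was 1.0 ± 0.404 CPM in Control and 22.9 ± 1.52 CPM in ETV5_OE (SD, n = 2), a 23.3-fold rise (log2 fold change 4.54, SE 0.32, edgeR adjusted p = 0.00151). The gene (ID 2119) lies on chromosome 3 from 186046314 to 186109089 in GRCh38. In the authors' deposited table, which compares quantile-normalized log2(FPKM + 1), its fold was 5.12 with an unadjusted p of 0.00317, on a scale that understates the change of genes this low in the controls.

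Among called genes above 10 CPM in Control, the largest fall was in another member of the same PEA3 subgroup of ETS factors. ETV1 (ID 2115; chromosome 7, 13891229 to 13991425), which is rearranged and highly expressed in LNCaP, fell 11-fold, from 318 ± 75.7 CPM to 28.8 ± 3.99 CPM (SD, n = 2; log2 fold change -3.46, SE 0.21, adjusted p = 0.00150). In the authors' deposited table the fold was -10.6. ETV4, the remaining member of the subgroup and chosen after its value was seen, stood at 0.66 CPM in Control and 1.46 CPM in ETV5_OE (adjusted p = 0.745).

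The next largest rises were in a plasma protein and a matrix protease. The copper-carrying plasma protein ceruloplasmin, CP (chromosome 3, 149162414 to 149221829), rose 18.8-fold from 3.05 ± 0.618 to 56.9 ± 3.74 CPM (log2 fold change 4.23, SE 0.22, adjusted p = 0.000824). The matrix metalloproteinase MMP7 (chromosome 11, 102520508 to 102530747) rose 18.6-fold from 3.04 ± 0.425 to 56.3 ± 19.5 CPM (adjusted p = 0.00252). AGR2, an endoplasmic reticulum protein of mucus-secreting epithelia (chromosome 7, 16791811 to 16804999), rose 6.97-fold to 34.8 ± 0.741 CPM (adjusted p = 0.00151). PLA2G4A, the cytosolic phospholipase A2 that releases arachidonic acid (chromosome 1, 186828949 to 186988981), rose 6.52-fold from 22.3 ± 6.63 to 145 ± 1.72 CPM (adjusted p = 0.00358). UGT2B10, a glucuronosyltransferase (chromosome 4, 68815994 to 68832023), rose 10.3-fold to 73.3 ± 13.9 CPM (adjusted p = 0.0202); the UGT2B genes are near-identical paralogs whose shared reads make single values uncertain. C4orf3 rose 4.56-fold (chromosome 4, 119296419 to 119304445; adjusted p = 0.00252) and the cancer-testis gene FMR1NB 4.63-fold (chromosome X, 147981337 to 148026665; adjusted p = 0.0423).

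Among the falls, the kinase MAPK13 (chromosome 6, 36130513 to 36144521) went from 5.94 ± 1.05 to 0.481 ± 0.208 CPM, 12.3-fold (log2 fold change -3.62, SE 0.47, adjusted p = 0.0251). The cysteine protease CTSO fell 8.58-fold (chromosome 4, 155924118 to 155953866; adjusted p = 0.0413), and the cancer-testis antigen MAGEA4 fell 7.78-fold from 128 ± 23.1 to 16.4 ± 4.34 CPM (chromosome X, 151912474 to 151925170; adjusted p = 0.00358). EFNB2, a transmembrane ligand of Eph receptors (chromosome 13, 106489745 to 106535662), fell 5.03-fold from 112 ± 4.42 to 22.3 ± 0.142 CPM (adjusted p = 0.00150). TMEFF2, a prostate-enriched transmembrane protein (chromosome 2, 191949046 to 192194933), fell 4.66-fold from 66.1 ± 12.5 to 14.2 ± 0.621 CPM (adjusted p = 0.00358). The transcription factor MAF, on chromosome 16 from 79202622 to 79600737, fell 5.60-fold from 35.3 ± 5.62 to 6.29 ± 1.55 CPM (adjusted p = 0.00731). The cold-sensing channel TRPM8, on chromosome 2 from 233917373 to 234019522, fell 5.09-fold from 19.0 ± 3.30 to 3.74 ± 1.04 CPM (adjusted p = 0.0202).

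**Figure D1:**
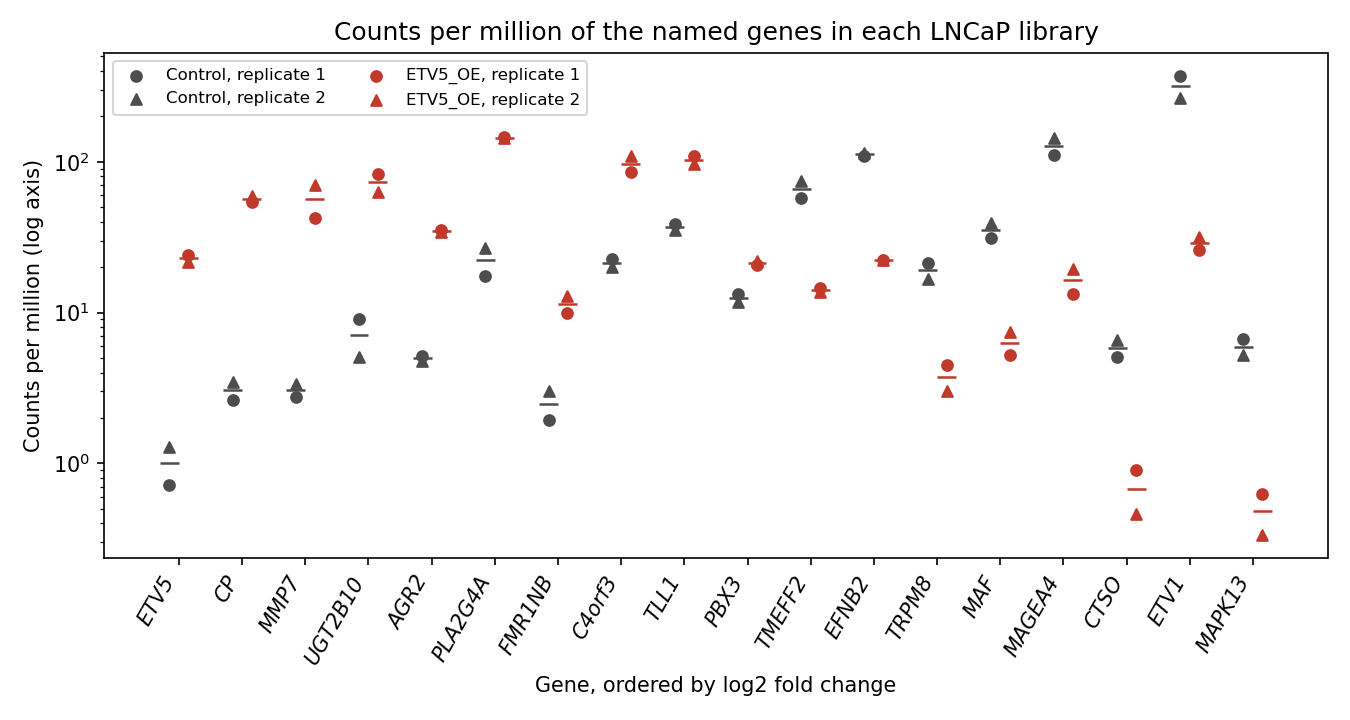
Normalised counts (CPM, log axis) of the named genes in each library, ordered by log2 fold change, with Control in grey and ETV5_OE in red; bars mark group means of 2 libraries. ETV5 lies near 1.0 CPM in Control and 22.9 CPM in ETV5_OE, and ETV1 at 318 and 28.8 CPM; PBX3 did not pass the threshold.

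Without ETV5_OE replicate 1 or without ETV5_OE replicate 2, edgeR called 0 genes (689 and 931 at an unadjusted p under 0.05), while leaving out Control replicate 1 or 2 gave 238 or 137 calls. With an ETV5_OE library left out, the spread came from the control pair alone. With a control library left out, it came from the ETV5_OE pair, which may be technical. With all libraries, the count was 22 without robust estimation, 24 against a 1.5-fold change, 38 with limma-voom, 232 with DESeq2, and 13 and 11 with limma on log2(FPKM + 1) and log2(FPKM + 0.1). The share of higher calls, 63.1% here, ranged from 53% with DESeq2 to 77.3% without robust estimation over the settings with any call.

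Luminal prostate epithelium genes had a median of -0.12 over 21 members (camera, down, adjusted p = 0.0400; adjusted p = 0.833 with an estimated correlation). None was called over all genes, and 2 were lower when adjusted over the list alone. Without Control replicate 2 or ETV5_OE replicate 1 the list was no longer called (adjusted p = 0.163 and 0.697). In the simulation, a planted list of independent genes also missed the threshold with an estimated correlation (camera adjusted p = 0.992). A miss in that setting, here and below, therefore does not decide. Basal epithelium genes showed no shift: of 6 tested none was called over all genes, 1 was higher adjusted over the list alone (LAMB3), the median was -0.04, and the test pointed up with adjusted p = 0.884.

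No neuroendocrine or neural list passed as higher. The 8 neuroendocrine markers tested, of 35 listed, had a median of -0.28 (camera, down, adjusted p = 0.0397; adjusted p = 0.833 with an estimated correlation). None was called over all genes; adjusted over the list alone 3 were lower, ENO2 (log2 fold change -0.87, SE 0.24), ONECUT2 (-0.49, SE 0.16) and PEG10 (-2.68, SE 0.73). PEG10 stood at 19.6 and 4.96 CPM in the 2 control libraries. The list lost its call without Control replicate 1 or ETV5_OE replicate 2 (adjusted p = 0.138 and 0.241), and with total counts only (0.0588). Of the others, 1 was below the count filter and 26 were not analysed here, so a switch from no reads to some would not be seen. The NEPC score genes had a median of 0.15 over 9 members tested, of 27 listed, with none called (camera adjusted p = 0.791). Of 33 neural stem and progenitor genes listed, 20 were not analysed here. None of the 12 tested was called, over all genes or over the list alone. Their median was 0.03 while the test pointed down (adjusted p = 0.639), with SOX9 at -0.82 (SE 0.42), MSI1 at -0.70 (SE 0.38) and MEIS1 at 0.29 (SE 0.28).

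Neuronal cytoskeleton and synapse genes had a median of -0.12 over 18 members tested, of 40 listed. Camera gave them as down (adjusted p = 0.0356), but not with an estimated correlation (adjusted p = 0.823). That estimate was -0.055, below the preset 0.01, so the miss does not show that members vary together. SYT4, a vesicle protein abundant in these cells, was the 1 member called, over all genes and over the list alone, and fell from 1292 ± 14.5 to 646 ± 38.9 CPM (adjusted p = 0.0352). Without Control replicate 1 or ETV5_OE replicate 2 the list was not called (adjusted p = 0.138 and 0.155). Axon guidance genes went both ways. EFNA5 rose 2.12-fold (adjusted p = 0.0218) and EFNB2 fell as given above. Adjusted over the list alone 1 of 27 was higher and 3 lower, the median was -0.05, and the list as a whole did not shift (down, adjusted p = 0.619).

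PBX3 and TLL1 are recalled as genes the study followed up and may have been picked from these libraries, so they are not independent evidence. TLL1, a procollagen-processing metalloprotease (chromosome 4, 165873237 to 166104457), rose 2.79-fold from 36.8 ± 2.41 to 103 ± 8.55 CPM (log2 fold change 1.48, SE 0.15, adjusted p = 0.00749). PBX3, a homeobox transcription factor (chromosome 9, 125747373 to 125967377), had 12.5 ± 1.03 CPM in Control and 21.3 ± 0.917 CPM in ETV5_OE. Its log2 fold change of 0.76 (SE 0.19), a 1.70-fold rise, did not pass (adjusted p = 0.276). On simulated counts the test recovered 0% of genes changed 1.5-fold and 32% at 2-fold, so the miss says little about a rise of this size. The authors' deposited table gives PBX3 a fold of 1.55 with an unadjusted p of 0.0102, and TLL1 a fold of 2.24.

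PEA3 and ETS invasion targets were called higher as a group by camera (adjusted p = 0.00543). They were not with an estimated correlation (adjusted p = 0.823). That estimate was 0.029, near the preset 0.01, so the miss does not show that members vary together. The median was 0.60 over the 10 members tested, of 18 listed. MMP7 was the 1 member called over all genes. Adjusted over the list alone 2 were higher, MMP7 and MMP10. The stromelysin MMP10 had a log2 fold change of 2.77 (SE 0.67) and stood at 0.685 and 2.77 CPM in the 2 control libraries. MMP7 and MMP10 lie near each other on chromosome 11, from 102520508 and 102770502, so their rises may not be independent. ETV1 fell in the same libraries, so a rise of this list cannot be assigned to higher ETV5 or to lower ETV1. The call held without each library in turn, with adjusted p from 0.00338 to 0.0365. The MAPK output and feedback list did not shift (median 0.13, up, adjusted p = 0.704). ETV1 was its 1 called member over all genes; adjusted over the list alone 3 of 14 were higher and 2 lower, among them the phosphatases DUSP5 (log2 fold change 1.51, SE 0.26) and DUSP6 (2.24, SE 0.51).

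The proliferation lists depended on the control libraries. S phase genes (median 0.22 over 42), G2 and M phase genes (0.15 over 52) and replication dependent histones (0.33 over 17) had none called over all genes or over the list alone, while camera gave them as up (adjusted p = 0.00228, 0.00346 and 0.00173; adjusted p = 0.833 with an estimated correlation for each). Without Control replicate 2 all 3 pointed down (adjusted p = 0.598, 3.33e-13 and 0.00132), and without Control replicate 1 all 3 pointed up (6.14e-11, 6.90e-39 and 4.36e-28). The histone H1 gene HIST1H1B, chosen after its values were seen, had 342 and 59.8 CPM in the control libraries and 439.9 and 225 CPM in the ETV5_OE libraries. Without ETV5_OE replicate 1 the S phase and histone calls were lost (adjusted p = 0.758 and 0.0600), and without ETV5_OE replicate 2 the G2 and M phase call (0.0954).

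Cytosolic ribosomal protein genes (median 0.14 over 74, up, adjusted p = 0.000547), the type I interferon response (0.27 over 29, up, adjusted p = 0.00466) and mitochondrially encoded genes (-0.28 over 15, down, adjusted p = 0.0118) also passed with camera and not with an estimated correlation (adjusted p = 0.833 each). None of their members was called over all genes, and adjusted over the list alone only OAS3 of the interferon list was, higher. Ribosomal protein genes pointed down without ETV5_OE replicate 2 (adjusted p = 0.248) and lost the call without Control replicate 2 (0.106). Interferon genes pointed down without Control replicate 1 (adjusted p = 0.384) and lost the call without ETV5_OE replicate 1 (0.0536). Mitochondrial genes pointed up without ETV5_OE replicate 1 (adjusted p = 0.758) and lost the call without Control replicate 2 (0.0779).

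The markers of other cells depended on single libraries. The stromal, endothelial and immune markers had a median of 1.22 over 6 members (camera, up, adjusted p = 0.0397; adjusted p = 0.833 with an estimated correlation), with none called over all genes or over the list alone. The call was lost without any library other than ETV5_OE replicate 2: adjusted p was 0.0660 and 0.154 without Control replicates 1 and 2, and 0.828 without ETV5_OE replicate 1. COL1A2, a chain of fibrillar collagen, stood at 41.4 CPM in ETV5_OE replicate 1 and at 0.326, 1.72 and 0.0835 CPM in Control replicates 1 and 2 and ETV5_OE replicate 2. COL3A1 stood at 15.5 CPM there and at 0.620, 1.38 and 0.960 CPM in the same order. Mesenchymal genes had a median of 0.36 over 15 members with none called (adjusted p = 0.175); the list was up without ETV5_OE replicate 2 (adjusted p = 0.000184) and pointed down without ETV5_OE replicate 1 (0.758).

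Stress, metabolic and other pathway lists did not pass. BBC3, which encodes the cell death protein PUMA, rose 3.33-fold to 18.7 ± 0.313 CPM (adjusted p = 0.0342) and was the 1 of 23 p53 targets called, over all genes and over the list alone, with the list unshifted (median 0.03, adjusted p = 0.526). No member was called over all genes in any of the following lists. Hypoxia and glycolysis genes had a median of 0.04 and a mean of -0.01 with the test up (adjusted p = 0.206), and SLC2A3 was lower over the list alone. The ER unfolded protein response had a median of 0.15 (adjusted p = 0.215), sterol synthesis 0.05 (0.511), the amino acid stress response -0.03 (0.859) and immediate early genes 0.13 (0.146), with JUNB higher over the list alone. Pluripotency and stemness genes had a median of -0.12 (adjusted p = 0.425). Wnt target genes had a median of 0.01 with the test down (adjusted p = 0.859) and TNFRSF19 lower over the list alone, and the Notch pathway a median of -0.02 with the test up (0.922). Leaving out Control replicate 1 made the amino acid stress, unfolded protein, hypoxia and immediate early lists pass as up (adjusted p = 5.72e-05, 7.32e-06, 9.89e-08 and 0.000645). Leaving out Control replicate 2 made the amino acid stress and hypoxia lists pass as down (3.74e-06 and 0.00491), and leaving out ETV5_OE replicate 2 made the unfolded protein list pass as up (0.0146).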

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

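Offsets for GC content and transcript length (53 calls), leaving out small structural RNAs (67 calls) and upper-quartile scaling of the list tests were chosen after the data were seen; the other alternatives were planned. With RLE, upper-quartile and total-count scaling, no filter and a CPM filter of 1, edgeR called 65, 67, 69, 56 and 61 genes, against 65. All 65 called genes kept their sign in every setting that tested them, which was 64 of them with FPKM values and GC and length offsets, and each scaling moved the median of all genes by less than 0.1 on the log2 scale. The counts moved further with DESeq2 (232 calls, 123 higher and 109 lower), limma-voom (38, with 9 lower), no robust estimation (22, 17 higher and 5 lower), the 1.5-fold threshold (24, 17 higher and 7 lower), limma on log2(FPKM + 1) (13, 9 higher and 4 lower) and limma on log2(FPKM + 0.1) (11, 7 higher and 4 lower); the cause was not tested. ETV5 kept its direction, and with log2(FPKM + 0.1) its log2 fold change was 4.02 with adjusted p = 0.0937. Of 18 alternatives, CTSO and PLA2G2A lost their call in 11 each, CCL20 in 9, FMR1NB in 8, BBC3, SLPI and SYT4 in 7, EFNA5 and TRPM8 in 6, UGT2B10 in 5, and the other called genes named here and in the report in 4 or fewer. The main fit was planned without the replicate numbers as pairs, and same-numbered libraries did not deviate together (correlation of deviations 0.0187). The library names of Control replicate 1 and ETV5_OE replicate 2 both end in R, a suffix that crosses the replicate numbers. No block by this suffix was fitted, so the replicate block does not cover it. With the replicate block 55 genes were called, 48 of them among the 65, and the ER unfolded protein response passed (adjusted p = 0.0169); no other list call reported here changed under it.

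Without each library in turn the calls ranged from 0 to 238, from 0 to 176 higher and from 0 to 62 lower, with 0 calls whenever an ETV5_OE library was left out, a fit in which that group has 1 library. Without Control replicate 1, 64 of the 65 genes were among the 238 called, and without Control replicate 2, 58 were among the 137. The ETV5 log2 fold change ranged from 4.14 to 4.98, with adjusted p = 0.0862 and 0.0674 without ETV5_OE replicates 1 and 2. Of the 26 lists reported here, 5 to 11 passed. PEA3 and ETS invasion targets, axon guidance, pluripotency and sterol synthesis kept their direction and their side of the threshold throughout. The adjusted p of the others ranged from 6.90e-39 to 0.0954 for G2 and M phase genes, 6.14e-11 to 0.758 for S phase genes, 4.36e-28 to 0.0600 for histones, 9.87e-18 to 0.248 for ribosomal proteins, 1.97e-08 to 0.758 for mitochondrial genes and 2.43e-13 to 0.384 for interferon genes. It ranged from 6.38e-06 to 0.828 for stromal, endothelial and immune markers, 0.000184 to 0.758 for mesenchymal genes, 0.00801 to 0.697 for luminal genes and 0.642 to 0.921 for basal genes. For neuroendocrine markers it ranged from 0.0106 to 0.241, NEPC score genes 0.373 to 0.828, neural stem genes 0.203 to 0.699, neuronal genes 0.0365 to 0.155, Notch genes 0.384 to 0.758, Wnt targets 0.607 to 0.828 and MAPK output 0.464 to 0.974. The stress lists ranged from 3.74e-06 to 0.873 (amino acid), 7.32e-06 to 0.828 (unfolded protein), 9.89e-08 to 0.697 (hypoxia), 0.138 to 0.828 (p53) and 0.000645 to 0.424 (immediate early). These fits have fewer samples.

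Camera called 11 lists of the 26, 0 with an estimated correlation and 0 with fry. With an estimated correlation the adjusted p was 0.823 for the PEA3 and neuronal lists, and 0.833 for the ribosomal, histone, S phase, G2 and M phase, interferon, mitochondrial, stromal, neuroendocrine and luminal lists. With fry it was 0.221 for the PEA3 and neuronal lists, 0.597 for the neuroendocrine and luminal lists, 0.742 for the stromal list, 0.801 for interferon genes, 0.808 for the ribosomal, histone, S phase and mitochondrial lists, and 0.858 for G2 and M phase genes. MAPK output pointed down with fry (adjusted p = 0.597). In the simulation a planted list lowered 1.5-fold also missed the threshold with both, at 0.992 and 0.539. A miss can therefore occur with a real shift of that size. The simulated genes varied independently, so the simulation cannot show how far misses of correlated lists can be discounted. Estimated correlations of the 11 lists ranged from -0.055 for neuronal genes to 0.98 for histones, against the preset 0.01. With total counts only, the neuroendocrine call was lost (adjusted p = 0.0588). The simulation recovered 0% of genes changed 1.5-fold, and depth was not varied in it.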

Other observations

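The gene families below, the single genes in the paragraph on the control libraries, the test of ETV1 reads assigned to ETV5, and the tests on distant neighbours, other splits' neighbours and pairs of called genes were chosen only after the results were seen. The test on genes next to called genes was fixed before its own value was seen, but after the genome-wide correlation of neighbours was.

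Among the 41 called rises were also those of the mucin-like Fc-gamma binding protein FCGBP (log2 fold change 2.01, SE 0.16), the membrane protein TM4SF1 (1.49, SE 0.15), the protease inhibitor SLPI (1.79, SE 0.23) and the chemokine CCL20 (1.98, SE 0.26). PIGR, the receptor that carries antibodies across epithelia, had 22.2 and 58.0 CPM in the control libraries and 132 and 203 CPM in the ETV5_OE libraries without passing (adjusted p = 0.660). The mucins MUC4 and MUC20, looked at with them, had log2 fold changes of -0.93 (SE 0.46) and -0.19 (SE 0.37). Among 10 genes of HLA class II antigen presentation, HLA-DRA rose 4.31-fold from 3.85 to 16.6 CPM (adjusted p = 0.0147), and its chaperone CD74 stood at 0.881, 0.573, 4.39 and 5.97 CPM in Control replicates 1 and 2 and ETV5_OE replicates 1 and 2 (log2 fold change 2.81, adjusted p = 0.0502). Of 12 phospholipase A2 genes, the secreted PLA2G2A rose 3.47-fold (adjusted p = 0.0477) beside PLA2G4A, and none was called lower. Of 18 MAGE genes MAGEA4 alone was called, and MAGEA3, the most abundant of them, had a log2 fold change of 0.03 (SE 0.17). Of 19 ETS factors only ETV5 and ETV1 were called. These family calls were the same under RLE, upper-quartile and total-count scaling, except that CD74 also passed under the last 2.

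The control libraries differed from each other in several abundant genes. TXNIP, which limits glucose uptake, stood at 14.6 CPM in Control replicate 1 and 520.3 CPM in Control replicate 2, with 15.6 and 69.4 CPM in ETV5_OE replicates 1 and 2. Its relative ARRDC4 stood at 8.90 and 48.0 CPM in the control libraries. The stress factor DDIT3 had 526 and 87.1 CPM and the heme oxygenase HMOX1 86.3 and 15.9 CPM in Control replicates 1 and 2. In the ETV5_OE libraries, DDIT3 stood at 372 and 222 CPM and HMOX1 at 32.0 and 43.2 CPM.

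ETV1 fell where ETV5 rose, and whether one ETS factor lowered the other was not tested. Assignment of ETV1 reads to ETV5 was excluded as the whole cause, since ETV5 rose by at most 23.2 CPM between libraries of the 2 groups and ETV1 fell by at least 233 CPM. Loss of the surrounding region of chromosome 7 on all its copies was excluded by 14 tested neighbours within 5 Mb. Their median was 0.033 (95% bootstrap interval -0.33 to 0.35). ETV1 is inserted in chromosome 14 near MIPOL1 in LNCaP. Lower activity of that region on all its copies was excluded by 22 neighbours within 2 Mb with a median of -0.083 (-0.24 to 0.05). Loss or lower activity of only the copy that carries the insertion cannot be judged, because these values sum over all copies. Loss of ETV1 alone, or growth of a subclone with less of it, was not tested and stays open.

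The 65 calls as a set could come from ETV5, from separate histories of the cultures, or from both. ETV1 fell from 318 to 28.8 CPM in the libraries where ETV5 rose to 22.9 CPM. Responses to higher ETV5 and to lower ETV1 therefore cannot be told apart. A GC or length trend was excluded as the whole cause, since 82.8% of the calls with known GC content and length (53 of 64) stayed called with offsets, while chance cannot be judged from 3 splits of the libraries, of which 1, the real one, called as many (65 against 0 in the highest other, with 649 and 469 genes at an unadjusted p under 0.05). Copy number differences cannot be told apart from an effect of ETV5: log2 fold changes of adjacent genes correlated at 0.118 across 14599 gene pairs, which are not independent, against 0.0526 in the highest other split, and the margin of 0.1 set for this test was wrong, because a simulated 1.5-fold gain of chromosome 13 moved the correlation only from -0.00118 to 0.0182. Genes next to called genes also leaned with them, with a signed median of 0.23 (70 of 98 above 0). Its 95% bootstrap interval, 0.16 to 0.31, straddles the bound of 0.3. For neighbours at least 10 kb away the median was 0.22 (0.13 to 0.42). Beside the 65 smallest p-values of the other splits it was 0.02 and 0.01. Those splits called 0 genes, so low medians there do not bear on the cause. Among the 61 called genes left after setting aside the UGT2B genes and 1 other pair of near-identical paralogs, 4 pairs within 1 Mb had the same direction, CP with TM4SF1 among them, and 0 had opposite directions, a number that 6.32% of 10000 random gene sets reached.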
